A study of Drosophila melanogaster with 4 samples.

How the data were processed

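Small RNAs were sequenced from 4 Drosophila melanogaster samples: ovaries of a Tailor knockout, ovaries of the w1118 strain, S2R+ cells soaked in double-stranded RNA against CG1091 (the annotation symbol of Tailor), and S2R+ cells soaked in double-stranded RNA against GFP. S2R+ is an established embryonic cell line. Per the labels' protocols, total RNA was extracted with TRIzol, RNA of 19 to 28 nt was purified on polyacrylamide gels, and libraries were made with a modified Illumina TruSeq small RNA kit. Each group held 1 library, so no difference reported here has a replicate check and no p-value is given.

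The deposited files list each distinct read sequence with its read count. Per the submitters' processing notes cutadapt was used. Its version and settings, and any aligner or genome build, were not given in the sources used here. The counts summed to 55475506 reads for the knockout ovary, 21263409 for the w1118 ovary, 29658049 for the knockdown cells and 19156984 for the GFP control cells. The lengths ran from 17 to 50 nt in each library.

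A genome sequence was not used here. MicroRNA arms were named by known mature sequences written down from general knowledge and placed on the annotated arms of Ensembl release 115 (assembly BDGP6.54), which lists 485 mature arms at 262 hairpins. Of 122 arms named this way, 114 had exactly the annotated length, against 43.1 on average (highest 62) when lengths were shuffled 10000 times. Recalled sequences that differed in length were trimmed, or extended by the most common next base of the control libraries, to the annotated length. Mirtrons, hairpins excised as short introns by splicing, were defined by an annotated arm within 3 nt of the end of an intron of at most 150 nt, or by name. All 11 mirtron arms ended in AG at the intron end. The remaining arms were 110 canonical arms, of which 64 were 3p and 46 were 5p, and 1 arm of a 3-prime-tailed mirtron that was left out of both sets.

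Reads of 18 to 33 nt without undetermined bases were assigned to the arm with the longest exact templated prefix, of at least 18 nt, with a 5-prime end within 2 nt of the arm's start. Up to 5 remaining bases at the 3-prime end counted as an untemplated tail. The template ended at the intron end for mirtrons and at the annotated end for other arms, or up to 2 bases beyond it where at least 20% of the control reads (and at least 20 reads) shared the extension base. Without a genome sequence, a base that is templated but rare cannot be separated from an added one. Conversely, U added in at least 20% of control reads counts as templated in canonical arms, but as a tail in mirtrons. For mir-1008-3p, U followed the template end in 60.2% of the control reads that reached it. U-tailed shares of mirtrons and canonical arms are thus not measured on the same footing. Reads that matched 2 arms equally well were left out, at most 0.0797% of the microRNA reads in any library. A U-tailed read carried 1 to 5 untemplated U and no other base. Tails of A, C or G only were counted the same way as background.

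Abundance is given as RPM, that is reads-per-million of the microRNA reads unless another total is named. Log2 ratios (knockout over w1118, knockdown over GFP control) carry exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson 95% intervals. Differences of shares carry intervals combined from the 2 exact ones. All of them cover counting error only. Arms needed 100 reads over the pair for a ratio, 2-fold was the rule of size, and an arm's U-tailed share needed 50 reads in both libraries. Where an arm had no read in a library, 3 reads were used as the floor. Medians of lists were placed among 10000 random lists of canonical arms matched on mean abundance (each member replaced by 1 of its 12 nearest arms, more for longer lists). The interval of the difference of medians came from 1000 Poisson resamples of the counts. Tails of other small RNAs were measured on reads that matched none of the named arms, grouped by their first 20 nt. The most common sequence of the pair was the parent where it had at least 20 reads and was 23 to 28 nt (piRNA length) or 21 nt (siRNA length). Reads of 21 nt were also translated on both strands and matched over 7 residues to GFP and to the B2 protein of an insect nodavirus, whose residues were written down from general knowledge and not checked against a database.

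The rule for named arms was fixed before the data were examined: per comparison, the 5 most abundant arms, the 8 largest rises and the 8 largest falls in log2 ratio among arms with 200 or more reads over the pair, the 5 largest falls and 5 largest rises in U-tailed share among 3p arms with 100 or more reads in each library, every mirtron arm with 50 or more reads over the pair, and members of 13 named lists with 200 or more reads. The text prints a selection of these and summarises the others by number. The alternatives tried were another scaling, other read minimums, untailed reads or distinct sequences only, other definitions of a tail, arms weighted by their control reads and leaving out the arm with most reads.

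The counting was tested on simulated reads. For the ovary comparison, over 109 arms, 20 of 20 arms changed 4-fold were recovered and 0 of 89 unchanged arms passed the 2-fold rule. For the S2R+ comparison, over 59 arms, 17 of 17 changed arms that passed the read minimum were recovered (20 were changed) and 0 of 42 unchanged arms passed. Both simulated libraries of a pair came from 1 profile with counting error only, scaled by the median ratio over arms and not by RPM. Unchanged arms could hardly reach 2-fold there, so the test covers the counting and not differences between single libraries. Simulated U-tailed shares were recovered with a median absolute error of 0.386 percentage points (ovary) and 0.367 (S2R+) where the template had no U among its last 2 bases. Where it had one, shares came out low by 2.25 and 1.85 percentage points on average, since a shortened read plus U can equal the template. This loss grows with the share, and most simulated shares were far above those of real canonical arms. Small RNAs matching Tailor itself, RPM of genome-matching reads and the division of reads into tRNA, transposon and other classes need a genome sequence and were not analysed here. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.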

Results

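The data comprised 4 small RNA libraries with 1 library per group: Tailor knockout ovary, w1118 ovary, Tailor knockdown S2R+ cells and GFP control S2R+ cells. Tailor (CG1091, FBgn0037470) is a terminal uridylyltransferase, an enzyme that adds U to the 3-prime ends of RNA. Its gene lies on 3R from 7083225 to 7086083 on the minus strand (BDGP6.54). The comparisons ask how microRNAs, their mirtron subset and the U tails at their ends differ when Tailor is removed in the ovary or depleted in cultured cells. With 1 library per group, every difference below compares libraries and has no replicate check.

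The targeted gene's own small RNAs were not analysed here. As a partial check of the labels, 21-nt reads encoding 7 residues of GFP, which dicing of GFP double-stranded RNA would yield from both strands, were counted. The GFP control cells held 166 such reads (184 RPM of 21-nt reads, 95% interval 157 to 214), but they were only 4 distinct sequences and 164 of the reads were antisense, so that dicing along both strands is not shown by them. The knockdown cells held 2, and neither ovary library held any among its 3290179 (knockout) and 872174 (w1118) reads of 21 nt, which allows up to 1.12 and 4.23 RPM. The GFP residues were recalled and not checked against a database. This check covers the GFP label only and says nothing of Tailor depletion.

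Reads of 19 to 28 nt made up 49.2% of the knockout ovary library, 31.3% of the w1118 ovary, 64.8% of the knockdown cells and 24.6% of the GFP control cells. Full-length 2S rRNA, a fly ribosomal RNA that runs near 30 nt on gels, took 15.9%, 30.1%, 9.76% and 33.1% of all reads in the same order. Within 19 to 28 nt the ovary libraries peaked at 22 and 23 nt, the length of most microRNAs, with 25.8% at 22 nt in w1118 and 18.3% in the knockout. The knockout ovary held more 23 to 28 nt reads (53.7% against 47.9%), the length range of piRNAs. In the cultured cells, 23-nt reads led with 27.7% in the knockdown and 33.5% in the control, and 21-nt reads took 23.1% against 19.2%. MicroRNA reads numbered 5748749, 2105117, 6035456 and 1752870, or 21.1%, 31.6%, 31.4% and 37.2% of the reads of 19 to 28 nt.

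**Figure D1:**
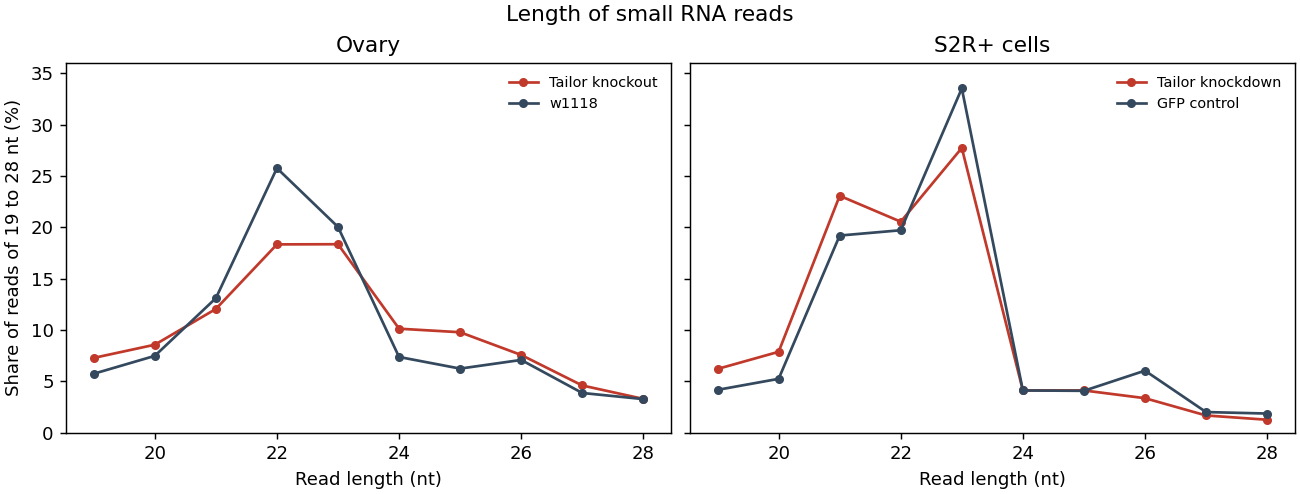
Share of the reads of 19 to 28 nt (%) at each read length (nt), in the ovary (left) and S2R+ cells (right), with mutant libraries in red and controls in blue. In w1118 ovary 25.8% of these reads were 22 nt long, against 18.3% in the knockout.

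In the knockout ovary the U-tailed share of mirtron 3p reads was 5.82% (95% interval 5.58 to 6.08, 34407 reads), against 23.5% (22.6 to 24.5, 7771 reads) in w1118. The difference was -17.7 percentage points (-18.7 to -16.7), and the control share was 4.03 times the knockout share. Part of this reflects which arms made up the reads: with each arm weighted by its w1118 reads, an alternative chosen after the data were seen, the knockout share was 11.5% and the difference -12.0. All 8 mirtron arms with 50 or more reads in both libraries had a lower U-tailed share in the knockout, and for 7 of them the interval of the difference excluded 0. The median of these arms was 3.18% in the knockout and 18.1% in w1118. Tails of 2 to 5 U were rare in both libraries, at 0.125% and 0.412%, so that nearly all of these tails were a single U.

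The largest fall in U-tailed share in the ovary was at mir-1010-3p, from 38.5% in w1118 to 15.7% in the knockout, and mir-1007-3p had 23.7% in w1118 and 2.34% in the knockout. mir-1014-3p had 47.1% in w1118 and 27.7% in the knockout, mir-1008-3p had 51.1% and 35.2%, and mir-1012-3p had 12.6% and 3.59%. mir-1003-3p lies in an intron of CG6695 on 3R (24658639 to 24658660, plus strand) and ends exactly at the 3-prime splice site. Its U-tailed share was 10.98% (9.37 to 12.8) in w1118 and 2.77% (2.41 to 3.17) in the knockout. mir-1006-3p, from an intron of VhaSFD, had 4.57% and 0.992%. The exception was mir-1009-3p, whose reads carried few U tails in either library (1.19% and 1.02%), a difference within counting error. mir-1013-3p had only 17 reads in w1118 and is not compared.

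Canonical 3p arms, which are released by Drosha rather than by splicing, were U-tailed in 0.697% of reads in the knockout ovary and in 1.58% in w1118 (difference -0.885 percentage points, -0.906 to -0.864). The w1118 share was 2.27 times the knockout share. With each arm weighted by its w1118 reads, the knockout share was 0.746%. At that weighting the fall relative to w1118 was no larger for mirtrons (11.5% against 23.5%) than for canonical 3p arms. Of 53 canonical 3p arms with enough reads, 47 had a lower share in the knockout, 36 of them with an interval below 0, and 5 had a higher one, none with an interval above 0. bantam-3p, a growth-promoting microRNA, had 1.20% in w1118 and 0.347% in the knockout. mir-14-3p had 1.21% and 0.312%, mir-8-3p 2.08% and 1.32%, and mir-958-3p 0.533% and 0.106%. The largest rise among 3p arms was at mir-87-3p, from 1.16% to 4.01%, with an interval of the difference from -0.369 to 4.77. Values for mir-307a-3p (3.92% in w1118, 4.597% in the knockout) and mir-308-3p (3.04% and 3.55%), and for mir-133-3p and mir-9b-3p (0.0534% and 0.134%), were higher in the knockout within counting error.

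As background, 5p arms, whose 3-prime ends face the hairpin loop, were U-tailed in 1.60% of reads in the knockout ovary and 1.93% in w1118. In the knockout that pooled share rests largely on mir-994-5p (12785 of 20630 U-tailed reads, against 2888 of 10198 in w1118). The medians of 41 arms were 0.752% and 1.57%, close to those of canonical 3p arms (0.688% and 1.53%), and 36 arms had a lower share, 22 with an interval below 0. A-tailed reads went the other way. They made up 5.32% of mirtron 3p reads in the knockout against 3.10%, and 3.99% of canonical 3p reads against 2.80%. G tails were at 0.340% and 0.3603% of mirtron 3p reads. C tails were more frequent in the knockout, with 12.6% of canonical 3p reads against 5.66%, and most of these (9.33% and 3.84%) were a C in place of the last annotated base. When U-only and C-only tails were counted together in reads that reach the annotated end, an alternative chosen after the data were seen, the mirtron difference was -24.3 percentage points and the canonical one -0.345. Counted together in all reads, the differences were -15.7 and, reversed, 6.05. C in place of the last base enters the count over all reads. C in place of a templated base beyond the annotated end enters both counts.

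In the knockdown S2R+ cells the U-tailed share of mirtron 3p reads was 3.58% (3.09 to 4.12, 5250 reads), against 20.4% (18.2 to 22.8, 1247 reads) in the GFP control. The difference was -16.9 percentage points (-19.3 to -14.6), or -15.1 with each arm weighted by its control reads. All 3 mirtron arms with 50 or more reads in both libraries had lower shares in the knockdown, each with an interval below 0. mir-1008-3p, which lies on 2R from 10885568 to 10885588 in an intron of CG18004, had 58.5% (52.4 to 64.3) in the control and 15.9% (12.96 to 19.2) in the knockdown. mir-1003-3p had 10.6% and 2.55%, and mir-1006-3p had 4.66% and 0.482%. With fewer reads, mir-1007-3p had 18.5% and 4.84%, and mir-1012-3p had 29.4% (10.3 to 56.0, 17 reads) and 2.17%. mir-1009-3p had 2.22% of 90 reads in the knockdown and none of 16 control reads. Without mir-1003-3p, which held most of these reads, the difference was -26.6 percentage points.

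**Figure D2:**
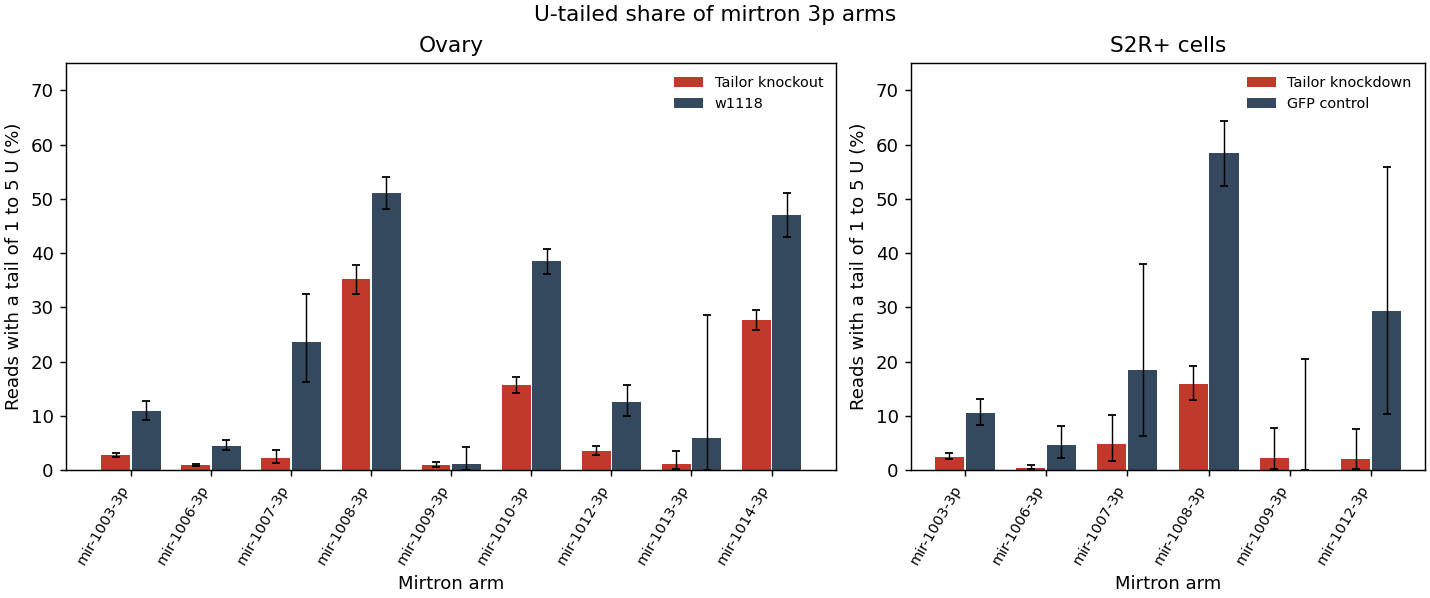
Share of reads with a tail of 1 to 5 U (%) for each mirtron 3p arm with at least 50 reads over the pair, in the ovary (left) and S2R+ cells (right), with bars for the mutant (red) and control (blue) libraries and exact 95% intervals for counting error. mir-1010-3p in the ovary stood at 38.5% in w1118 and 15.7% in the knockout, and mir-1008-3p in the cells at 58.5% in the control and 15.9% in the knockdown.

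Canonical 3p arms in the knockdown cells were U-tailed in 0.506% of reads against 1.53% in the control (difference -1.03 percentage points, -1.05 to -1.01), and 29 of 30 arms had a lower share, 23 with an interval below 0. The largest falls among them were at mir-970-3p, from 8.05% to 1.39%, at mir-317-3p, from 7.33% to 1.21%, and at mir-998-3p, from 5.97% to 0.717%. mir-14-3p had 3.10% in the control and 0.409% in the knockdown, mir-184-3p 3.97% and 1.21%, and bantam-3p 0.867% and 0.333%. bantam-3p alone held most microRNA reads of these cells, and without it the canonical difference was -2.26 percentage points. With each arm weighted by its control reads, the canonical share was 0.526% in the knockdown. At that weighting the fall relative to the control was larger for mirtrons of the cells (5.38% against 20.5%). mir-307a-3p (2.38% and 2.68%) and mir-308-3p (3.24% and 3.21%) had nearly equal shares in both libraries.

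The 5p arms of the cells were U-tailed in 0.651% of reads in the knockdown and 1.43% in the control, and 13 of 17 arms had a lower share, 10 with an interval below 0. mir-33-5p was the only 5p arm with a higher share in the knockdown and an interval above 0 (2.91% against 2.47%), and mir-9c-5p (9.11% against 8.66%), mir-252-5p (23.6% against 20.5%) and mir-276a-5p (0.189% against 0) were higher within counting error. A tails differed little, with 1.07% of canonical 3p reads in the knockdown and 1.02% in the control, and 2.51% and 2.41% of mirtron 3p reads. C tails stood at 13.6% of canonical 3p reads in the knockdown and 1.75% in the control, again mostly as a C in place of the last base (10.4% and 1.18%). With U-only and C-only tails counted together in reads that reach the annotated end, the mirtron difference was -21.4 percentage points and the canonical one -0.0295. Counted together in all reads, the differences were -13.0 and, reversed, 10.8.

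Tailor is known for a preference for RNAs ending in G. In the ovary, the 12 3p arms whose annotated last base is G had a median change in U-tailed share of -2.31 percentage points, at the 0.375th percentile of random lists of 3p arms, and 11 of them were lower in the knockout. Arms ending in U had a median of -0.851 (23 arms, percentile 49.3), those ending in C -0.781 (12 arms, percentile 65.6) and those ending in A -0.571 (14 arms, percentile 92.0). G-ending arms also started from the highest median share, 4.80% in w1118, with 2.94% in the knockout. The other medians were 1.21% and 0.484% (U), 1.80% and 0.856% (C), and 1.77% and 0.803% (A). Relative to w1118, the median of G-ending arms thus fell least, although it fell most in percentage points. The A-ending arms include 2 mirtrons, mir-1007-3p (-21.3) and mir-1008-3p (-15.9), whose templates end in G at the intron end, 1 base further. The template of G-ending mir-314-3p was extended to a U. So were those of C-ending mir-2a-3p, mir-2c-3p and mir-11-3p and of U-ending mir-13a-3p and mir-13b-3p. In these arms a single U after the annotated end does not count as a tail. The templates of C-ending mir-2b-3p and mir-989-3p were extended to a G and an A. Those of A-ending mir-4-3p, mir-311-3p and mir-312-3p were extended by A. U-tailed shares of arms with U among their last 2 bases came out low on simulated reads, so that U-ending arms are not measured on the same footing as the others. The simulated loss averaged 2.25 percentage points (ovary) and 1.85 (S2R+), but it grows with the share. Most simulated shares were far above the real medians of U-ending arms (0.484% in the knockout ovary and 1.21% in w1118), so its size does not carry over. Of the 12 G-ending arms, 6 were mirtrons, and among canonical 3p arms alone the 6 G-ending arms had a median of -1.42, at the 8.54th percentile. In the cells only 4 arms ended in G, with a median of -3.88 (percentile 12.3), against -2.15 for 14 U-ending arms (percentile 27.0), -1.32 for 10 C-ending arms (percentile 72.3) and -1.10 for 5 A-ending arms (percentile 78.4). The median share of G-ending arms was the highest in the control cells too (5.30%, against 2.45% in the knockdown). That of U-ending arms was 3.42% in the control and 0.688% in the knockdown. Of the A-ending arms of the cells 1 was likewise a mirtron, mir-1008-3p. Among canonical arms of the cells, 2 ended in G, with a median of -1.80 at the 54.1st percentile.

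Mirtron arms were more abundant among microRNAs in the knockout ovary. Their median log2 ratio was 1.02 over 9 arms, against -0.21 for canonical arms, a difference of 1.23 (0.95 to 1.30). This median lay at the 99.98th percentile of abundance-matched lists of canonical arms, whose middle 95% ran from -1.56 to 0.55. 7 of the 9 arms were higher and 5 were at least 2-fold higher. Scaled to reads of 19 to 28 nt, the median was 0.43, 6 arms were higher and 2 at least 2-fold higher, and the ratio of all mirtron reads was 1.08. Summed over all mirtron arms, reads were 5985 RPM in the knockout and 3691 in w1118, a ratio of 1.62 (1.58 to 1.66). The rises were largest for mir-1013-3p (log2 2.37, 1.66 to 3.17), mir-1009-3p (2.099, 1.87 to 2.33), mir-1006-3p (1.38), mir-1007-3p (1.04) and mir-1003-3p (1.02). mir-1014-3p (0.61) and mir-1012-3p (0.43) were higher by less. Lower in the knockout were mir-1008-3p (-1.26, -1.38 to -1.14) and mir-1010-3p (-0.82, -0.91 to -0.73). Counted as distinct sequences, the difference of medians was 0.41.

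In the knockdown cells the median log2 ratio of 6 mirtron arms was 0.53 against 0.15 for canonical arms, a difference of 0.38 (0.15 to 0.58), at the 87.5th percentile of matched lists. None of the 6 reached 2-fold. mir-1009-3p (0.71, -0.07 to 1.58), mir-1012-3p (0.65, -0.10 to 1.49) and mir-1007-3p (0.42, -0.19 to 1.07) had intervals that included 0. mir-1006-3p was at 0.61 (0.41 to 0.82) and mir-1003-3p at 0.44 (0.32 to 0.56). mir-1008-3p was lower, at -0.79 (-0.997 to -0.573), as it was in the knockout ovary. The mirtron total was 870 RPM in the knockdown and 711 in the control, a ratio of 1.22 (1.15 to 1.30), or 1.03 when scaled to reads of 19 to 28 nt.

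**Figure D3:**
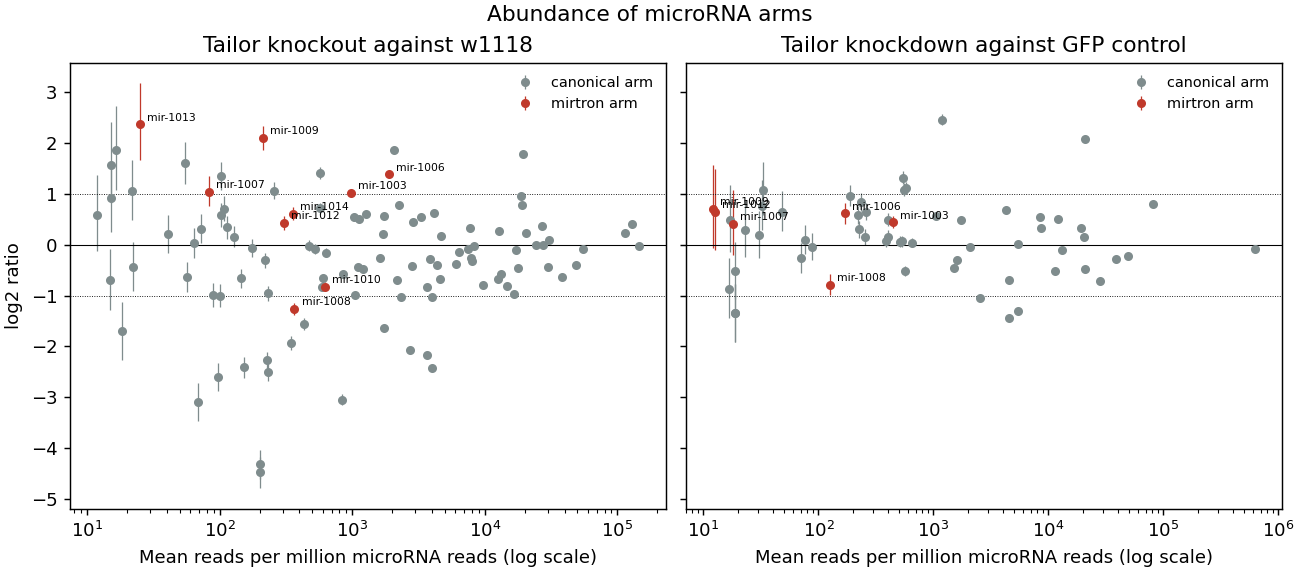
Log2 ratio of mutant over control for each microRNA arm with at least 100 reads over the pair, against its mean RPM (log scale), in the ovary (left) and S2R+ cells (right), with mirtrons in red, canonical arms in grey and vertical lines for 95% intervals of counting error. Dotted lines mark the 2-fold rule; 5 of the 9 ovary mirtrons and none of the 6 in S2R+ cells lie above it.

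Across all microRNAs of the ovary, 76 of 109 arms with 100 or more reads differed by less than 2-fold, 14 were at least 2-fold higher in the knockout and 19 at least 2-fold lower. The 5 most abundant arms were mir-14-3p (log2 -0.02), bantam-3p (0.40), mir-8-3p (0.23), mir-13b-3p (-0.09) and mir-958-3p (-0.39). Among arms with 200 or more reads, the largest rises after the mirtrons were mir-9b-3p (1.87), mir-79-3p (1.79, from 8682 to 29946 RPM), mir-987-5p (1.60), mir-313-3p (1.40) and mir-983-5p (1.35). The largest falls were mir-124-3p, a neuronal microRNA (-4.48, from 387 to 17.4 RPM), mir-968-5p (-4.31), mir-1002-5p (-3.09), mir-6-3p (-3.05), mir-1000-5p (-2.60), mir-5-5p (-2.51), mir-314-3p (-2.42) and mir-286-3p (-2.41). Scaled to reads of 19 to 28 nt, an alternative chosen after the data were seen, 6 arms were at least 2-fold higher and 43 at least 2-fold lower, since every ratio then shifts by -0.59 and the median of all arms was -0.70 in place of -0.11. The directions given here are relative to all microRNAs. Under the median-ratio factor the counts were 16 higher and 16 lower.

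By group, 3 of 4 arms of the embryonic mir-309 cluster were at least 2-fold lower in the knockout ovary, mir-6-3p, mir-5-5p and mir-286-3p, while mir-4-3p stood at 0.15 (-0.05 to 0.36), and the median of -2.46 lay at the 2.44th percentile of matched lists. The mir-310 cluster, which is expressed in the germline, had a median of 0.64 over 4 arms (percentile 99.6), led by mir-313-3p. Scaled to reads of 19 to 28 nt, which shifts every ratio by -0.59, most of that median is lost and mir-313-3p (1.40 before) falls under 2-fold. Of 8 arms of testis microRNAs 3 were at least 2-fold higher and none lower, with a median of 0.58 (percentile 100). The 3 were mir-982-5p (1.85), mir-983-5p (1.35) and mir-961-5p (1.05), at up to 148 RPM in the knockout, and scaled to reads of 19 to 28 nt the list's median falls just under 0. The mir-9 family went both ways. mir-9b-3p and mir-79-3p were at least 2-fold higher, mir-9a-5p was at -2.07, and the median of 7 arms was -0.00 (percentile 86.7).

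Follicle-cell microRNAs stayed within 2-fold (3 arms, median -0.08, percentile 50.9), with mir-318-3p at -0.08, mir-994-5p at 0.79 and mir-989-3p at -0.97. The let-7 complex had a median of -0.40 (3 arms, percentile 53.4), and let-7-5p, a timing regulator of metamorphosis, stood at -0.40. Of 8 arms of the mir-2 seed family 2 were at least 2-fold lower, mir-6-3p and mir-13a-3p (-1.93), with a median of -0.38 (percentile 18.9). Broadly expressed microRNAs had 1 of 12 arms at least 2-fold lower, mir-34-5p (-2.18), and a median of -0.17 (percentile 50.3). Both arms of the cluster of mir-275 and mir-305 (median -0.52, percentile 33.3), both of the cluster of mir-279 and mir-996 (0.19, percentile 71.8), the 3 of the cluster of mir-12, mir-283 and mir-304 (0.08, percentile 79.05) and both muscle arms (0.03, percentile 71.2) stayed within 2-fold.

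In the S2R+ cells 50 of 61 arms differed by less than 2-fold, 6 were at least 2-fold higher in the knockdown and 5 at least 2-fold lower. bantam-3p alone stood at 603773 and 642777 RPM (log2 -0.09). The other most abundant arms were mir-14-3p (0.81), mir-184-3p (-0.23), mir-8-3p (-0.28) and bantam-5p (-0.71). The largest rises were mir-965-3p (2.46, 2.35 to 2.58), mir-282-5p (2.09, from 7934 to 33727 RPM), mir-9c-3p (1.32), mir-8-5p (1.11), mir-970-3p (1.09) and mir-281-2-5p (1.08). Among arms with 200 or more reads, the largest falls were mir-317-3p (-1.44, -1.47 to -1.40), mir-33-5p (-1.30), mir-9c-5p (-1.04) and mir-1008-3p (-0.79), and with fewer reads mir-958-3p and mir-994-5p (both -1.34, from 64 and 47 reads each). Scaled to reads of 19 to 28 nt, which shifts every ratio by -0.25, 3 arms were higher and 7 lower. Under the median-ratio factor 3 were higher and 6 lower, and with untailed reads only 8 were higher and 2 lower. None of the 61 arms measured in both comparisons was at least 2-fold higher in both or lower in both.

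By group in the cells, the mir-2 seed family had all 7 arms within 2-fold (median 0.19, percentile 67.1, below 0 when scaled to reads of 19 to 28 nt), with mir-2b-3p at 0.54 and mir-13b-3p at -0.47. The mir-9 family had mir-9c-3p at least 2-fold higher and mir-9c-5p at least 2-fold lower among 6 arms (median 0.03, percentile 25.1). Broadly expressed microRNAs had mir-8-5p higher and mir-33-5p lower among 12 arms (median 0.00, percentile 22.5). The cluster of mir-275 and mir-305 (median 0.03, percentile 44.7), the cluster of mir-279 and mir-996 (0.42, percentile 83.3) and the cluster of mir-12, mir-283 and mir-304 (0.15, percentile 16.8) stayed within 2-fold. The 2 libraries also differed in 21-nt reads encoding B2, a protein of insect nodaviruses, matched by residues recalled and not checked against a database (918 RPM of 21-nt reads in the knockdown, 160 in the control). The follicle-cell, mir-309 cluster and testis lists had 1 arm each with 100 reads, at -1.34, 0.19 and -0.51, and the let-7 complex, mir-310 cluster, muscle and nervous system lists had none.

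Other small RNAs differed in directions that in part turned with the definition used. In the definitions tried, piRNA-length reads of the ovary stayed more U-tailed and siRNA-length reads of the cells less, relative to their controls. Piwi-interacting RNAs are mostly 23 to 28 nt long. At that length, among reads outside the named microRNA arms, those with only U beyond the parent's end made up 7.06% in the knockout ovary and 4.49% in w1118. In the knockdown cells they made up 5.07%, and in the GFP control 6.29%. Among those starting with U, as most piRNAs do, the cells turned to 3.10% and 2.42%, the direction of the ovary (5.81% and 3.77%). At 21 nt, the length of siRNAs, they made up 6.03% and 9.04% in the ovary and 4.12% and 7.82% in the cells, but tails of 2 to 5 U were more frequent in the knockout ovary (0.704% and 0.479%). Among 21-nt reads starting with U the differences were small, with 3.95% and 4.56% in the ovary and 2.62% and 2.68% in the cells, the latter within counting error. Extensions by A only at 21 nt moved the same way in the ovary (4.39% in the knockout and 6.53% in w1118) and the opposite way in the cells (3.83% and 2.88%). Without a genome sequence, templated extensions are part of these shares. Only 122 of the 485 annotated mature arms were named, so reads of other microRNA arms can be part of them too. Parents were chosen on the summed reads of a pair, and most counted reads came from the mutant library. At piRNA length in the ovary these were 4168362 against 827020, and at 21 nt in the cells 2152477 against 295659. The ends of the parents thus follow the mutant libraries more than the controls. Its effect on the shares was not tested. Reads equal to esi-2.1, an siRNA of an endogenous hairpin transcript, stood at 126 RPM in the knockout ovary, 74.1 in w1118, 168 in the knockdown cells and 213 in the GFP control.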

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

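The tests of U read as C, of fewer captured additions, of library preparation, of low-abundance arms, of lost tails and of tissue mix below were all chosen after the results were seen.

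Several results went opposite ways in the 2 tissues, and with 1 library per group these differences were not tested. Log2 ratios were positive in the S2R+ cells and negative in the ovary for mir-8-5p (1.11 and -0.66), mir-276a-5p (0.58 and -0.99), mir-965-3p (2.46 and -1.03) and mir-996-3p (0.51 and -0.58), the arms with at least 200 reads and 0.5 log2 in both. These 4 were picked by that rule after their values were seen. The U-tailed share of piRNA-length reads differed by -1.21 percentage points in the cells and by 2.56 in the ovary, but among reads starting with U it differed by 0.680 in the cells and 2.04 in the ovary, in the same direction.

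Some signals lay outside the measured microRNAs. A sequence equal to vertebrate miR-142-5p stood at 1216 RPM of all reads in the knockout ovary (647 in w1118) and 141 in the knockdown cells (6.73 in the GFP control), while 23 other vertebrate microRNAs searched had 0, 0, 2 and 1 reads. Its origin is not known here. Reads holding the end of the 5-prime adapter stood at 2369 RPM in the knockout ovary (267 in w1118) and 179 in the knockdown cells (16.7 in the control). Reads of 21 nt encoding the nodavirus B2 protein stood at 918 RPM of 21-nt reads in the knockdown cells (890 to 946, 1986 sense and 2084 antisense reads) against 160 (135 to 189) in the control. The ovaries held 2.13 and 3.44.

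The first pattern is the lower share of U tails without Tailor. If U tails had been read as C, counting both together should remove most of the fall, but for mirtrons the difference stayed at -15.7 percentage points in the ovary and -13.0 in the cells (-9.09 and -11.0 with each arm weighted by its control reads). Capture of fewer additions of every kind, as the whole cause, is argued against by A-tailed shares of mirtrons at 1.72 times the control (1.499 to 1.97) in the ovary and 1.05 times (0.699 to 1.61) in the cells, where U-tailed shares stood at 0.248 and 0.175 times (with each arm weighted by its control reads, A at 2.15 and 1.26 times and U at 0.489 and 0.263), although G-tailed shares in the cells were lower too (0.369 times, 0.149 to 0.968). For canonical arms the 2 readings cannot be told apart. U and C tails together differed by 6.05 in the ovary and 10.8 in the cells, since C in place of the last base enters that count. At the annotated end they differed by only -0.345 and -0.0295, but C in place of a templated base beyond that end still enters there. mir-11-3p, which has such a base, carried C tails in 17.5% of reads in the knockout ovary and 10.3% in w1118. Shares corrected for U read as C kept differences of -0.819 and -0.904. Loss of Tailor may underlie the mirtron pattern, and a strain difference could apply to the ovary pair alone, since both cell libraries carry the same cell line label, but other differences between single libraries stay open. Several of those ran the same way in both pairs. Adapter reads were higher in the mutants (2369 against 267 RPM in the ovary, 179 against 16.7 in the cells). Full-length 2S rRNA was lower (15.9% against 30.1%, and 9.76% against 33.1%). The 2 pairs are thus not independent checks with respect to library preparation.

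The second pattern is the C in place of the last annotated base in both mutant libraries. Mirtron arms, which end in G or A, showed it too, at 2.53% in the knockout ovary and 0.888% in w1118. In the cells they had 2.21% in the knockdown and 0.802% in the control. The sequence equal to miR-142-5p, which is not a fly microRNA, carried such an excess at its last base, a U. It was 16.7 percentage points (16.1 to 17.3) in the ovary pair and 21.6 (17.3 to 23.7) in the cell pair. This is consistent with library preparation or sequencing as the source, unless that sequence was exposed to the same cells. That sequence does not test a last base other than U, and no biological explanation was tested.

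The third pattern is the higher abundance of mirtrons in the knockout ovary. A rise of low-abundance arms in general is argued against by the 99.98th percentile among abundance-matched lists. Loss of U tails as the reason for the rise was taken to predict a negative rank correlation of log2 ratio and change in share. The correlation was 0.619 over the 8 arms with enough reads, with an interval (-0.229 to 0.933) that includes 0. A fall in percentage points cannot exceed an arm's w1118 share, which was 1.19% for mir-1009-3p and 51.1% for mir-1008-3p. For that reason too the correlation cannot decide for or against lost tails as the reason. mir-1008-3p and mir-1010-3p lost U tails and were less abundant. Another tissue mix cannot be told apart either, since the testis list was also higher (median 0.58) while neuronal mir-124-3p was lower, and the strains may differ in more than Tailor.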

How the results depend on the processing

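Chosen after seeing the data were the scaling to reads of 19 to 28 nt, reads that reach the annotated end, U and C tails together, the correction for U read as C, leaving out arms extended by U, canonical arms alone for the terminal base, first base U, and arms weighted by their control reads. Of 94 alternatives 39 stayed within the counting interval (or 1.5 times a count), 51 moved and 4 reversed, and the cause was not tested except where stated. Some of the 39 could not move. Another scaling leaves the mirtron difference of medians unchanged, and mirtrons chosen by name only were the same arms. No paired analysis was possible because each group held 1 library.

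Counts of arms at least 2-fold changed were 1 in each comparison for distinct sequences, where only 71 and 29 arms passed the minimum, and 18 in the cells at 20 reads. Scaling to reads of 19 to 28 nt gave 6 higher and 43 lower in the ovary and 3 higher and 7 lower in the cells, by a shift of every ratio (-0.59 and -0.25). The mirtron abundance difference was 1.42 with untailed reads and 0.41 with distinct sequences (6 arms) in the ovary. With distinct sequences 1 mirtron arm was left in the cells (0.14), which says nothing of the 6-arm result.

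The lower U-tailed share of mirtrons kept its direction in every alternative run in both comparisons. For 2 to 5 U in the cells it rests on 3 tailed reads in each library, and the interval (-0.647 to 0.0368) includes 0. In percentage points (ovary, then cells) it was -14.97 and -8.01 as the median of arms, -0.287 and -0.183 for 2 to 5 U, -3.83 and -8.66 for distinct sequences, -21.1 and -26.6 without the arm with most reads (mir-1006-3p, mir-1003-3p), -22.9 and -22.6 for reads that reach the annotated end, -15.7 and -13.0 for U or C tails, -24.3 and -21.4 for U or C tails in reads that reach the annotated end, -12.0 and -15.1 with arms weighted by their control reads, and -18.8 in the ovary for any tail containing U.

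For canonical 3p arms the same order gave -0.843 and -1.72 as the median of arms, -0.0766 and -0.09496 for 2 to 5 U, -0.854 and -1.31 for any tail containing U, -2.97 and -3.46 for distinct sequences, -0.857 and -1.16 for reads that reach the annotated end, -0.819 and -0.904 after correction for U read as C, -0.819 and -0.972 without arms extended by U, -0.836 and -1.01 with arms weighted by their control reads, and -2.26 in the cells without bantam-3p. It reversed to 6.05 and 10.8 for U or C tails, since C in place of the last base enters that count, and at the annotated end was -0.345 and -0.0295. There, C in place of a templated base beyond the annotated end still enters.

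G-ending arms had -8.21 and -8.01 by the last base of the most common untailed read (11 and 3 arms, percentiles 0.005 and 0.25), and -1.42 and -1.80 for canonical arms alone. Both -8.21 and -8.01 are the values of a mirtron, mir-1003-3p. For piRNA-length reads 2 to 5 U gave 0.106 and -0.257, and first base U gave 2.04 and, reversed, 0.680. For siRNA-length reads 2 to 5 U gave 0.226 (reversed) and -0.876, and first base U gave -0.617 and -0.0558.

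Planned but not run, for want of a genome sequence here, were RPM of genome-matching reads, any read inside the hairpin on the arm side, unique genome matches and the alternatives for the targeted gene. Matching to hairpin arms alone was already the way reads were assigned. Depth limits the mirtron shares of the cells, with 1247 reads in the control.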
